A study of Galaxea fascicularis with 5 samples.

How the data were processed

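Single-cell RNA libraries of the stony coral Galaxea fascicularis were analysed, 1 library for each of 5 tissue samples: coenosarc replicate 1, coenosarc replicate 2, budding tip, early polyp and mature polyp. The coenosarc is the sheet of living tissue that joins neighbouring polyps of a colony. Per the labels, coenosarc replicate 1, the budding tip and the mature polyp were sampled in August and coenosarc replicate 2 and the early polyp in September, so stage and month are partly tied together. The labels speak of several colonies and do not say which samples came from the same one.

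Per the labels' protocols, micro-dissected tissue of healthy colonies was digested with enzymes to single cells and loaded on a BD Rhapsody system, which captures single cells in microwells with barcoded beads and tags each captured molecule with a unique molecular identifier (UMI). The sequencer was a GeneMind FASTASeq, per the labels. The aligner, genome build, annotation and cell caller are not given in the sources used here; the submitters' processing notes name Seurat 5 without a role. The deposited matrices hold whole-number UMI counts per gene and cell and are not normalised; the authors call them filtered, without stating how. The rest of what the authors deposited, of no measured unit (other), is a list of cell numbers and a list of gene identifiers (IDs) per library. Both columns of the gene lists hold the same ID, so 0 of 30451 IDs were paired with a name. The 21 lists of marker and pathway genes fixed before the data were examined could therefore not be matched to any ID, and neither list tests nor cell type names are given.

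Barcodes with at least 200 detected genes were kept, which left 98214 of 159193 barcodes and 130920214 of 140233964 UMIs. Kept cells per library numbered 21716, 15904, 26401, 20466 and 13727 in the order coenosarc replicate 1, coenosarc replicate 2, budding tip, early polyp and mature polyp, with 25220945, 21806620, 34319690, 32774849 and 16798110 UMIs. A count of 3 UMIs, the upper limit that a count of 0 allows, was worth between 0.0874 and 0.179 CPM (UMIs scaled by the library total). Doublets were scored in each library with Scrublet in scanpy 1.11.5 at an expected rate of 6%. Its automatic threshold marked 1 of 98214 cells and so did not work here; cells were kept, and leaving out the 6% of cells with the highest scores in each library was added as an alternative after this was seen.

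For clustering, counts were scaled to 10000 per cell and log-transformed, the 2000 most variable genes were centred within each library, and 30 principal components, 15 nearest neighbours (umap-learn 0.5.12) and Leiden clustering at resolution 0.5 (igraph 0.11.9) were used with a fixed seed. This gave 24 clusters of at least 50 cells. Clusters have numbers in order of size and no cell type names. On simulated cells of 5 types (6250 cells) the clustering step recovered the types with an adjusted Rand index of 1.00. These types had unlike profiles (r at most 0.348), so the recovery of clusters of like profile was not tested. On the real cells, clustering under other settings was less stable. Its adjusted Rand index with the main clusters ran from 0.458 (cells thinned to 300 UMIs) to 0.883 (without the 6% of cells with the highest doublet scores). Shares of cells are given with exact 95% binomial intervals, which cover counting error only. Clusters whose mean profiles correlated above 0.75 were also merged, as an alternative chosen after the clusters were seen.

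UMI counts were summed over the kept cells of each library, and within each cluster with at least 20 cells in every library, because cells are not replicates. Sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05). Of 30451 IDs, 21725 passed the filter in the whole-library tests. The comparison of the 2 coenosarc libraries with the 3 others had 3 residual degrees of freedom. In that comparison and its tests within clusters, the residual spread also holds differences among the 3 bud and polyp stages and between months. The comparisons of each single stage with coenosarc came from a fit with 4 stages, which had 1 residual degree of freedom, from the coenosarc pair; the lone libraries are assumed to vary like that pair. Nothing in the labels says that samples of a group came from separate colonies, so p-values measure the spread between these samples. Standard errors of log2 fold changes were taken from the fold change and the square root of its quasi-F statistic. CPM values are library sums scaled by library size alone.

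The clustering, the whole-library tests, the rule for stage-high genes and the prediction from cluster shares were tested on simulated data. Tests within clusters, of the month difference and of adjacent IDs were not. With 200 genes changed among 21725, the test of coenosarc against the 3 others recovered 7% of the genes set at 2-fold and 59% of those set at 4-fold, with 3 false calls. Contrasts of single stages recovered 0% at 2-fold, and at 4-fold 12% for the budding tip and 15% each for early and mature polyp, with 0 false calls for the budding tip and the mature polyp and 2 for the early polyp, 11.8% of its calls. The comparison of both polyp libraries with the 3 others recovered 7% and 69%, with 2 false calls. In these simulations all libraries shared a mean profile apart from the changed genes and varied independently. They held no month or colony differences and no choice among pairings, so false calls from those were not measured. The rule for stage-high genes found 30 of 30 genes set 8-fold higher in 1 library, with 0 false. Those simulated libraries differed by counting error alone, and 8-fold is well above the 4-fold of the rule. How many genes differences between libraries, months or colonies would mark was not tested.

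Genes were named by a rule set before the data were examined, which for IDs without names allows at most 2 that rose and 2 that fell per comparison: the largest log2 fold changes among genes with adjusted p under 0.05, mean CPM of at least 10 and the stage's library (or all 3 bud and polyp libraries) beyond both coenosarc libraries, or, where fewer than 5 genes passed, those with the smallest unadjusted p, said not to pass. Exceptions are stated where they occur. Stage-high genes were defined by size alone: at least 20 CPM in that library and at least 4-fold above each other library.

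The comparison of the early and mature polyp libraries with the 3 others was added after all 10 ways of setting 2 libraries against 3 had been computed. Alternatives tried were RLE size factors (edgeR), library size alone, no filter, at least 10 CPM in 2 or more libraries, all barcodes, at least 500 genes per cell, libraries thinned to the smallest total, DESeq2 1.42.0, sampling month as a covariate, stage position as a linear term, leaving out each library, and for clusters resolution 1.0, 1000 variable genes, no centring and cells thinned to 300 UMIs. The latter left out 1878, 621, 1810, 1054 and 407 cells below that depth, in the library order above.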

Results

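Tissues along the course of asexual budding in Galaxea fascicularis, a reef coral whose polyps arise from a shared tissue sheet, were profiled by single-cell RNA sequencing. The coenosarc, which lies between polyps, was sampled in 2 libraries (August and September). The active budding tip (August), the early polyp (September) and the mature polyp (August) had 1 library each, so values of these stages have no replicate. Between 13727 and 26401 cells per library passed a minimum of 200 genes, with 16798110 to 34319690 UMIs per library and a median of 721 to 880 UMIs per cell. The files do not pair gene identifiers with names, so cell populations are given as numbered clusters and genes as IDs.

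Each coenosarc library was closest to a bud or polyp library of its own month. Summed over cells, coenosarc replicate 1 and the budding tip, both of August, had 230 of 11138 genes more than 2-fold apart (2.07%), the fewest of the 10 library pairs. Coenosarc replicate 2 was closer to the early polyp, with 692 genes (r 0.909), than to the budding tip, with 799 (r 0.906). The 2 coenosarc libraries, of different months, differed by more than 2-fold in 836 genes. Coenosarc replicate 1 and the early polyp, which differ in both stage and month, were farthest apart, with 1392 genes. Pearson's r across genes, which are not independent replicates, was 0.966 for coenosarc replicate 1 and the budding tip, 0.893 for the coenosarc pair and 0.807 for coenosarc replicate 1 and the early polyp. Counts of every pair differed by far more than sampling noise, with a chi-square per degree of freedom of at least 56.2, so all 5 were used as separate libraries.

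**Figure D1:**
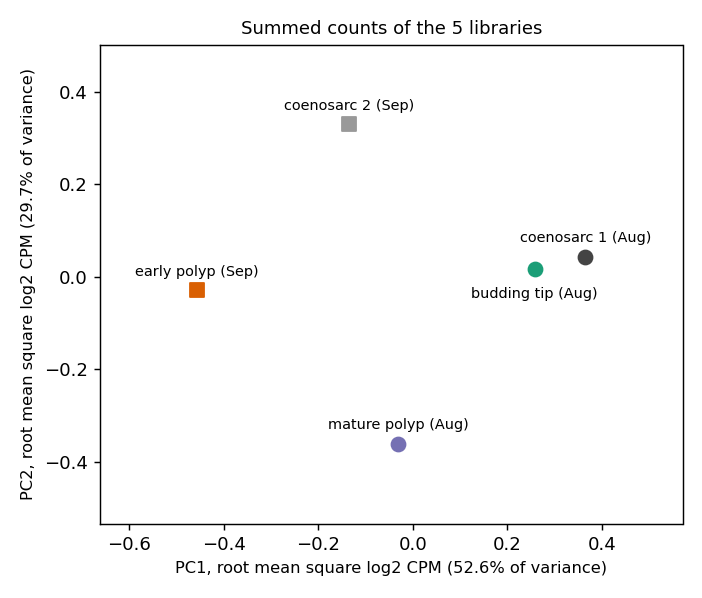
Principal components of the summed counts of the 5 libraries, from log2(CPM + 5) of 11138 genes with a mean above 10 CPM; PC1 (52.6% of variance) is on the horizontal axis and PC2 (29.7%) on the vertical, circles are August and squares September libraries. Coenosarc replicate 1 and the budding tip lie together at 0.37 and 0.26 on PC1, and the early polyp lies at the other end at -0.46.

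Cells fell into 24 clusters of 238 to 14914 cells, and the libraries differed in the share of cells in several of them. With 1 library per bud or polyp stage, stage cannot be told apart from month or colony in these shares. Cluster 10 was larger in each bud or polyp library than in the coenosarc library of its month, by 3.12-fold in the budding tip, 9.38-fold in the mature polyp and 6.06-fold in the early polyp. It held 0.272% of cells (exact 95% interval 0.207 to 0.350) in coenosarc replicate 1, 0.848% (0.741 to 0.967) in the budding tip and 2.55% (2.29 to 2.83) in the mature polyp. In September it held 2.09% (1.88 to 2.33) in coenosarc replicate 2 and 12.7% (12.2 to 13.2) in the early polyp. With 1000 variable genes the direction in the budding tip turned, at 1.37% against 1.61% in coenosarc replicate 1. Over all clustering alternatives the ratio was 0.848 to 10.9 in the budding tip, 2.41 to 45.6 in the mature polyp and 5.18 to 8.30 in the early polyp. Cluster 7 was largest at the intermediate stages, with 7.76% (7.44 to 8.09) of budding tip and 6.36% (6.03 to 6.70) of early polyp cells, against 2.78% and 3.24% in the coenosarc libraries and 2.65% in the mature polyp.

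Cluster 12 was smaller outside coenosarc. It held 4.91% (4.63 to 5.21) and 4.44% (4.12 to 4.77) of cells in the coenosarc libraries, and 2.95% (2.75 to 3.16) in the budding tip, 1.86% (1.68 to 2.05) in the early polyp and 2.13% (1.90 to 2.39) in the mature polyp. Cluster 24, of 238 cells, went the same way, from 0.341% and 0.534% to 0.155%, 0.0733% and 0.168%. Clusters 13 and 16 also lay lower in all 3 bud and polyp libraries than in both coenosarc libraries, but in each the nearest 2 libraries had overlapping intervals. No cluster lay higher in all 3. For clusters 12, 16 and 24 the exact two-sided permutation p was 0.1, the smallest that 2 libraries against 3 can give. The 4 clusters of 24 that separated the groups compare with 4.80 (20%) that chance gives, and the number was 5 of 21 with clusters of like profile merged, 3 at resolution 1.0 or without the cells of highest doublet score, and 2 with 1000 variable genes, without centring or with cells thinned to 300 UMIs.

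Polyp libraries differed in other clusters. Cluster 20 held 2.37% (2.12 to 2.64) of mature polyp cells, 4.81-fold above coenosarc replicate 1, while the early polyp stood at 0.910-fold of coenosarc replicate 2. The coenosarc libraries themselves differed, with 0.493% (0.404 to 0.595) in replicate 1 and 1.28% (1.11 to 1.47) in replicate 2. With cells of at least 500 genes the matched cluster held 2.73% against 1.23% (2.23-fold) in the mature polyp, and 2.85% against 1.90% in the early polyp, which turned the direction there. Cluster 21 was higher in both polyp libraries than in the coenosarc library of their month, 2.94-fold in the mature and 3.51-fold in the early polyp, and lower, at 0.557-fold, in the budding tip; over the clustering alternatives the early polyp ratio was 3.44 to 7.93. Cluster 17 was 10.7-fold larger in the early polyp than in coenosarc replicate 2, and 1.24-fold larger in the mature polyp than in coenosarc replicate 1. Over the clustering alternatives these ratios were 9.18 to 22.7 and 1.03 to 2.32. The coenosarc libraries differed here too, with 0.976% (0.850 to 1.12) in replicate 1 and 0.264% (0.190 to 0.357) in replicate 2. The early polyp held 2.81% (2.59 to 3.05). The mature polyp, at 1.21% (1.03 to 1.41), had an interval that overlapped that of coenosarc replicate 1. Over all clusters, 4 were higher and 8 lower in every bud or polyp library than in the coenosarc library of its month, against 8 of 24 in total that chance gives. In clusters 21 and 22, 18.4% and 20% of the cells were among the 6% with the highest doublet scores of their library, the highest shares of the 24 clusters.

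Both September libraries lay apart from all August libraries in 9 of 24 clusters. Coenosarc replicate 1 with the budding tip lay apart from the others in 11 and the polyp pair in 8, where chance gives 4.80 for any pair. Clusters 2, 5, 11, 15, 18, 19 and 23 were smaller in both September libraries than in all August libraries, and clusters 3 and 22 were larger. Cluster 18 had 1140 August and 5 September cells and cluster 19 had 1136 and 4. Some clusters were nearly single libraries and may be that library rather than a type: coenosarc replicate 2 gave 99.2% of cluster 8 and the early polyp 77.4% of cluster 3. Cluster 2 had a profile close to both, and merged, these 3 clusters held 17.8% and 33.2% of cells in the coenosarc libraries, 25.1% in the budding tip, 38.1% in the early polyp and 25.2% in the mature polyp.

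**Figure D2:**
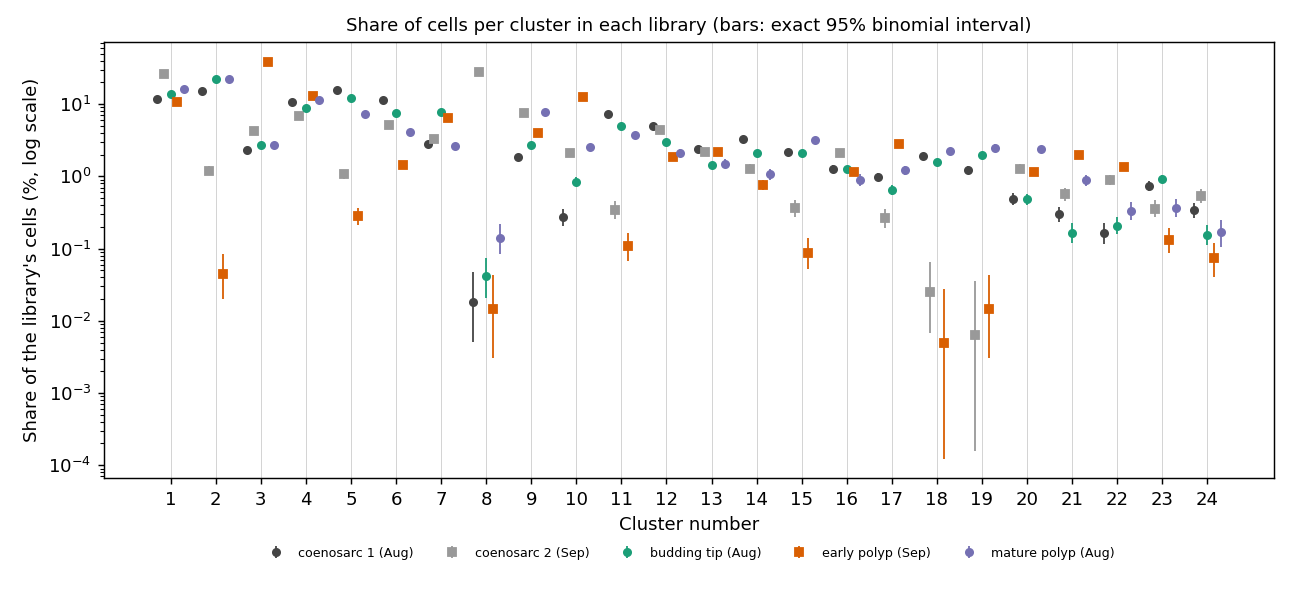
Share of each library's cells (percent, log scale) in clusters 1 to 24, with exact 95% binomial intervals that cover counting error only; circles are August and squares September libraries, and colours are stages. In cluster 10 the early polyp stands highest at 12.7%, in cluster 12 both coenosarc libraries stand above the other 3, and in clusters 18 and 19 both September libraries lie far below the August libraries.

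No gene passed the test between coenosarc and the bud and polyp libraries as a group. The spread in this test holds differences among the 3 bud and polyp stages and between months, so 0 calls do not mean no difference. Of 21725 genes, 0 were called by edgeR, with 753 at an unadjusted p under 0.05, and 84 were called by DESeq2 (73 higher and 11 lower in bud and polyp libraries). All 3 bud and polyp libraries lay above both coenosarc libraries in 1343 genes and below both in 1847, together 14.7% of genes where chance gives 20%. The genes with the smallest p are given as values that did not pass. Gfa293670 had 5.15 ± 1.64 CPM in coenosarc (SD, n = 2) and 59.4 ± 34.9 in the others (SD, n = 3), a log2 difference of 3.57 (SE 0.61, edgeR adjusted p = 1.00), and 94.7% of its UMIs lay in cluster 7. Gfa266370 had 16.0 ± 0.373 and 34.4 ± 5.59 CPM. In the other direction Gfa298720 had 26.4 ± 0.897 and 11.7 ± 0.0554 CPM, with 50.5% of its UMIs in cluster 12, and Gfa128230 had 27.0 ± 12.4 and 7.71 ± 0.791 CPM. Month as a covariate in edgeR also gave 0 calls, with 1753 at an unadjusted p under 0.05, and without the early polyp 1 gene was called, Gfa229200.

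The budding tip, set against coenosarc alone, gave no call either. Of 21725 genes edgeR called 0, with 423 at an unadjusted p under 0.05, and DESeq2 called 22. Gfa293670 stood at 97.6 CPM in the tip (3349 UMIs) against 6.30 and 3.99 CPM in coenosarc, a ratio of 18.7 to the pooled coenosarc counts (counting interval 16.4 to 21.3; log2 difference 4.33, SE 0.41, edgeR adjusted p = 0.123). Gfa153110 stood at 92.3 CPM against 14.7 and 9.35, and at 211 CPM in the mature polyp. Gfa229200 was nearly missing from the tip at 0.641 CPM (22 UMIs) against 74.98 and 83.9 CPM in coenosarc (log2 difference -6.87, SE 0.56, edgeR adjusted p = 0.0875), and Gfa271980 stood at 0.932 against 19.8 and 26.2 CPM. In the mature polyp Gfa229200 and Gfa271980 were at 0.833 CPM each and in the early polyp at 55.9 and 38.7 CPM. Scaling by library size alone called Gfa229200, and without a filter on low counts 166 genes were called.

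The early polyp had 75 genes that differed from coenosarc, nearly all higher. In edgeR, 73 rose, with log2 fold changes of 2.73 to 9.95 and a median of 4.56, and 2 fell. The largest rises among genes of at least 10 CPM were in Gfa040950, from 0.0396 and 0.275 CPM in coenosarc (1 and 6 UMIs) to 147 CPM (4805 UMIs), and Gfa280430, from 0.119 and 0.0917 CPM (3 and 2 UMIs) to 41.3 CPM. The ratios to the pooled coenosarc counts were 985 (counting interval 478 to 2451) and 389 (166 to 1200), with edgeR adjusted p of 0.0107 and 0.00964. Gfa225640 fell from 141 and 164 to 8.21 CPM (log2 fold change -4.14, SE 0.53, edgeR adjusted p = 0.0348). The other gene that fell, Gfa308390, had a mean of 3.15 CPM, under the minimum for named genes, and is given because the count is small. Of the 73 that rose, 15 had their highest level in cluster 10, 14 each in clusters 3 and 21 and 12 in cluster 4. Clusters 3, 10 and 21 are rich in early polyp cells, so these pooled levels do not place the rises in a cell population. The test rests on 1 early polyp library, and the count was 11 with a stricter filter, 23 with cells of at least 500 genes, 35 without the cells of highest doublet score, 135 with library size alone, 891 without a filter and 381 with DESeq2.

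In the mature polyp 56 genes differed from coenosarc, 52 higher and 4 lower. Rises had log2 fold changes of 2.76 to 7.69 with a median of 4.22. Gfa108120 rose from 4.20 and 2.43 to 726 CPM (log2 fold change 7.69, SE 0.56, edgeR adjusted p = 0.00926), with 79.3% of its UMIs in cluster 4. Gfa135460 rose from 4.12 and 3.85 to 600 CPM (log2 fold change 7.14, SE 0.47, edgeR adjusted p = 0.00922), with 77.3% of its UMIs in cluster 9. Gfa229200 fell to 0.833 CPM (log2 fold change -6.67, SE 0.56, edgeR adjusted p = 0.0131) and Gfa271980 to the same level (log2 fold change -4.88, SE 0.62, edgeR adjusted p = 0.0433). Genes that rose were most often highest in cluster 3, followed by clusters 2 and 4. These levels were pooled over all libraries, and the early polyp gave 77.4% of the cells of cluster 3. They therefore do not place the rises in cells of the mature polyp. The test rests on 1 mature polyp library, with the spread taken from the coenosarc pair of different months, and the count was 7 with a stricter filter, 9 with cells of at least 500 genes, 13 without the cells of highest doublet score, 97 with library size alone, 631 without a filter and 238 with DESeq2.

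By size alone, the early polyp had the most genes of its own. At 20 CPM or more and at least 4-fold above each other library, 50 genes marked the early polyp, 16 the mature polyp, 0 the budding tip and 0 both coenosarc libraries together. Of the 50, 32 had their highest level in cluster 10, where 72.9% of the cells came from the early polyp. Of 18472 genes with a mean above 1 CPM, 4.04% were highest there. Genes picked as high in the early polyp tend to be high in such a pooled profile, so this does not place them in cluster 10. Gfa207890 had 859 CPM in the early polyp (Poisson 95% interval 849 to 869), 5.33-fold above the next library, and Gfa127340 had 653 CPM (645 to 662), 7.16-fold above the next, the mature polyp. Of the 16 genes of the mature polyp, the 2 most abundant were Gfa108120, at 726 CPM (713 to 739), 4.34-fold above the early polyp, and Gfa135460, at 600 CPM (588 to 611), 7.81-fold above it. These intervals cover counting error only. Differences among the budding tip, early polyp and mature polyp were not tested for these genes, and the tests of single stages above were against coenosarc alone. At 2-fold, 197, 111, 19 and 5 genes met the rule in the early polyp, mature polyp, budding tip and coenosarc. Without coenosarc replicate 2 the early polyp had 104, and without coenosarc replicate 1 the remaining coenosarc library had 22.

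Within clusters, the genes called between coenosarc and the bud and polyp libraries lay in cluster 11 alone, and cluster 11 gave calls for 9 of the 10 pairings of libraries, with up to 89. In 18 clusters with at least 20 cells in every library, edgeR called 12 genes, 4 higher and 8 lower, all in cluster 11, which had 22 cells and 6504 UMIs in its smallest library, the early polyp. In the other 17 clusters edgeR called 0, with 3888 of 128966 tests at an unadjusted p under 0.05, and DESeq2 called 167. In cluster 11 DESeq2 called 1, and edgeR without the early polyp called 0. Over all clusters the count was 2 without the early polyp, 62 without coenosarc replicate 1, 50 without coenosarc replicate 2 and 48 without the budding tip.

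The early and mature polyp, 1 of each month, had a set of genes in common that were low in coenosarc and budding tip. Set against the other 3 libraries, they differed in 36 of 21725 genes, 35 higher and 1 lower (edgeR adjusted p under 0.05), with log2 fold changes of 2.02 to 6.11 and a median of 3.71 among the genes that rose. Gfa065870 rose from 0.588 ± 0.468 CPM (SD, n = 3) to 44.0 ± 2.30 (SD, n = 2), a log2 fold change of 6.11 (SE 0.65, edgeR adjusted p = 0.0489), and 62.5% of its UMIs lay in cluster 3. Gfa265580 rose from 10.01 ± 4.89 to 612 ± 234 CPM, a log2 fold change of 5.93 (SE 0.55, edgeR adjusted p = 0.0425), with 89.1% of its UMIs in cluster 21. Gfa225640 fell from 167 ± 27.4 to 10.3 ± 2.91 CPM, a log2 fold change of -4.08 (SE 0.31, edgeR adjusted p = 0.0425). This grouping was chosen after all 10 pairings of the libraries had been computed, of which it gave the most calls. The edgeR adjusted p-values make no allowance for that choice, and those of all 36 genes lay between 0.0425 and 0.0489. The polyp grouping did not give the most genes at an unadjusted p under 0.05 (edgeR). These numbered 2010 for the polyp pair, 4721 for the September pair and 2746 for coenosarc replicate 1 with the budding tip.

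Polyp libraries also differed from the others within clusters. In 9 of 18 clusters edgeR made calls, 274 summed over clusters, 198 higher and 76 lower. Cluster 3 had 50 calls, cluster 21 had 49, cluster 9 had 36, cluster 5 had 27 and cluster 4 had 16. The calls in cluster 5 were not particular to the polyp pair. Coenosarc replicate 1 with the budding tip gave 74 there, the September pair 42 and coenosarc replicate 2 with the mature polyp 38. The smallest library of cluster 5 had 57 cells and that of cluster 21 had 44. Cluster 11, on 22 cells in its smallest library, had 89, of which 29 were higher and 60 lower, and the other clusters together had 185, of which 169 were higher and 16 lower. The early polyp gave 77.4% of the cells of cluster 3, and with clusters 2, 3 and 8 merged there were 81 calls, 62 higher and 19 lower. With month as a covariate there were 989 calls in 13 clusters, 598 higher and 391 lower. Coenosarc replicate 1 with the budding tip, set against the others, gave 165 calls in 8 clusters. In cluster 9 all 36 and in cluster 4 all 16 calls of the polyp pair were higher in polyps. With month as a covariate cluster 9 had 55 higher and 20 lower, and cluster 4 had 70 and 5. Over whole libraries, month as a covariate gave 267 calls, of which 230 were higher and 37 lower, and all 36 genes were among them. The count was 0 without coenosarc replicate 1 or without the budding tip (1368 and 1389 genes at an unadjusted p under 0.05 in edgeR), 4 without the early polyp, 74 without coenosarc replicate 2 and 83 without the mature polyp, and 0 with a filter of at least 10 CPM in 2 or more libraries, with 1017 at an unadjusted p under 0.05.

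**Figure D3:**
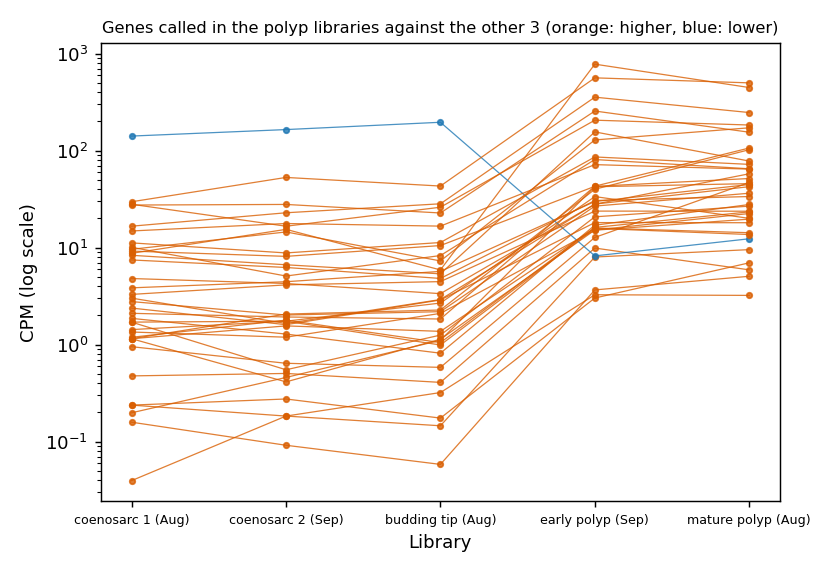
CPM (log scale) of the 36 genes called between the polyp libraries and the other 3, with 1 line per gene across the 5 libraries. The 35 orange genes stand higher in both polyp libraries, and the blue gene, Gfa225640, falls from 141, 164 and 196 CPM to 8.21 and 12.3.

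**Figure D4:**
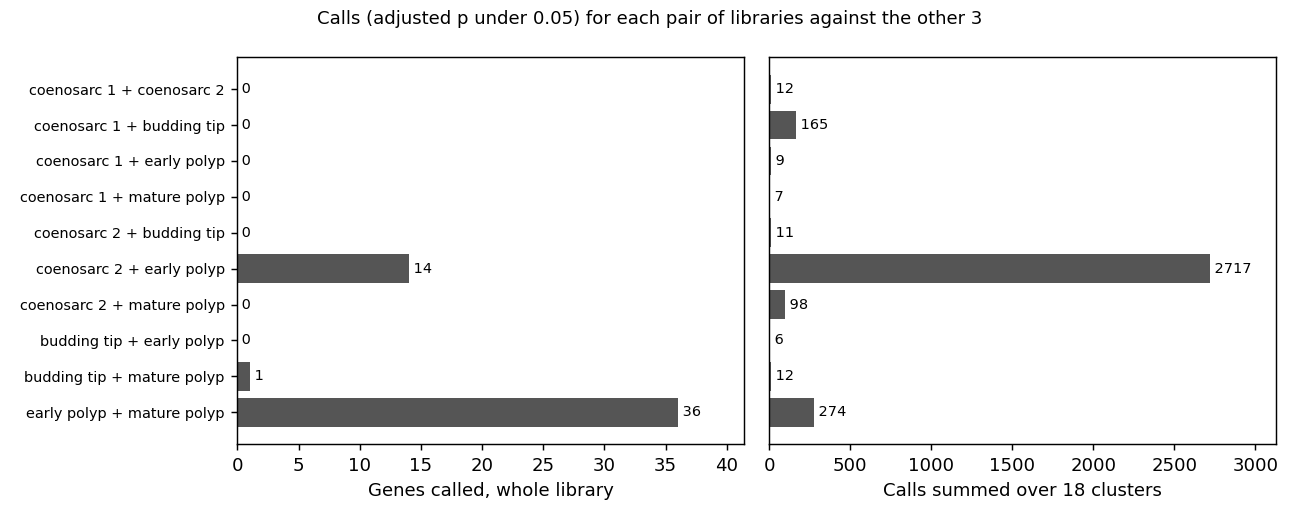
Number of calls (edgeR, adjusted p under 0.05) for each pair of libraries set against the other 3, over whole libraries (left) and summed over 18 clusters (right). Over whole libraries the polyp pair gives the most, 36, and the September pair of coenosarc replicate 2 and early polyp gives 14. At an unadjusted p under 0.05 (edgeR, not drawn) the September pair has 4721 genes and the polyp pair 2010. Within clusters the September pair gives 2717, of which clusters 1 and 6 hold 1824 and 730. Over the other 16 clusters it gives 163 against 274 for the polyp pair, 89 of them in cluster 11.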

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

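The merging of clusters with like profiles and the comparison of September with August were chosen after results of the same data were seen; the tests of the month difference were written down before their own values were computed.

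Beyond their exact intervals, shares of 3 clusters moved one way in both August bud and polyp libraries against the August coenosarc library, and the other way in the September early polyp against the September coenosarc library; the difference was not tested. Cluster 2 moved by 0.53 in the budding tip, 0.53 in the mature polyp and -4.76 in the early polyp (log2 ratio of shares), a gap of 5.29 between the August mean and the early polyp. In cluster 9, which moved by 0.53, 2.04 and -0.90 (a gap of 2.18), the opposite directions held over the clustering alternatives, with share ratios of 1.33 to 1.74, 3.52 to 4.95 and 0.519 to 0.626. Cluster 1 moved by 0.23, 0.47 and -1.31, a gap of 1.66. For clusters 1 and 2 the opposite directions depended on the clustering. Cluster 2, with 199 September and 12314 August cells, had a profile close to clusters 8 and 3 (r 0.881 and 0.780 across genes), and merged with them the early polyp was higher than coenosarc replicate 2 (38.1% against 33.2%), the direction of the August libraries. Cluster 1 merged with cluster 6 (r 0.783) was lower in all 3 bud and polyp libraries than in the coenosarc library of their month: 21.5% and 20.6% against 23.4%, and 12.1% against 31.5%.

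Calls between September and August libraries within clusters lay mostly in 2 clusters of like profile: of 2717 calls summed over clusters (edgeR, adjusted p under 0.05), cluster 1 had 1824 and cluster 6 had 730. The other 16 clusters had 163, fewer than the 274 of the polyp pair (185 without cluster 11), and 9 of the 18 clusters had 0. Few calls do not mean a small difference. At an unadjusted p under 0.05 (edgeR), cluster 3 had 2079 of 11039 genes and 0 calls, against 1136 genes and 50 calls for the polyp pair. Such genes were more numerous for September against August than for the polyp pair in each of the 18 clusters except clusters 10 and 21. Unequal depth was argued against for cluster 1, since 1751 genes were called with every library thinned to the smallest total in that cluster. A single shift of the same genes in every cluster, as free RNA or tissue handling could give, stays open: the September change correlated between unlike clusters with a median r of 0.389 (across genes, which are not independent; quartiles 0.273 and 0.481 over 144 cluster pairs), between the bounds set for and against it. Month, colony and library batch cannot be told apart here, and a seasonal response of the coral was not tested.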

How the results depend on the processing

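Leaving out the cells of highest doublet score, and each alternative of the polyp comparison, were chosen after seeing the data. No called direction was reversed. Unless a cause is named, the cause was not tested.

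Counts of called genes moved most. With library size alone the counts were 1 for the budding tip, 135 for the early polyp and 97 for the mature polyp. Without a filter on low counts they were 166, 891 and 631, and 164 for the polyp pair. With at least 10 CPM in 2 or more libraries they were 11 for early polyp, 7 for mature polyp and 0 for the polyp pair. With cells of at least 500 genes they were 23, 9 and 19, and without the cells of highest doublet score 35 for early and 13 for mature polyp. DESeq2 called 84 genes between coenosarc and the 3 others, 22 in the budding tip, 381 in the early and 238 in the mature polyp, 726 in the polyp pair and 168 within clusters. Month as a covariate gave 267 for the polyp pair. Leaving out 1 library gave 0 to 1 calls for coenosarc against the others, 0 to 83 for the polyp pair, and 2 to 62 within clusters; leaving out either coenosarc library gave 94 and 129 stage-high genes. Stage-high genes at 2-fold numbered 332 over all stages. Clusters lower in all bud and polyp libraries numbered 5 with like clusters merged, 2 with 1000 variable genes, 2 without centring and 2 with cells thinned to 300 UMIs.

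Over the named genes, called or not, 172 alternatives left the direction and the call or its absence as they were, 23 lost a call and 13 gained one. The sign of the share difference between bud or polyp and coenosarc libraries was kept in each clustering alternative that matched a cluster, except for cluster 1 (6 of 9) and clusters 4 and 9 (8 of 9 each). Alternatives that kept the main clusters and only left out cells could hardly turn a sign. Alternatives that did not recover a cluster are not counted: cluster 15 was matched in 3 and cluster 19 in 4. All 36 genes of the polyp pair kept their sign in each alternative that tested them, 31 of them with the 10 CPM filter. This could hardly turn out otherwise, since each gene lay on the same side of all other libraries in both polyp libraries. The calls themselves fell to 0 without coenosarc replicate 1, without the budding tip or with the 10 CPM filter. The single-stage tests could not be run without either coenosarc library, since no residual degrees of freedom are left. No paired analysis was possible because the groups share fewer than 2 replicate numbers. The labels number replicates for coenosarc alone and do not say which samples came from the same colony. Genes under a mean of 10 CPM, the minimum for named genes, were among the rises of both the early and the mature polyp. Whether depth limits the tests of such genes was not tested.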

Other observations

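The comparison of polyp libraries with the rest and the tests of adjacent IDs were chosen after the result was seen; the depth and cluster share tests of the polyp genes were written down before their values were computed.

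Of the 35 genes higher in both polyp libraries, 8 had their highest level in cluster 3 and 5 each in clusters 4, 9, 20 and 21, so no single cluster held most of them. By size alone, at 4-fold and 20 CPM, 80 genes were higher and 2 lower in both polyp libraries than in the other 3, against 20 and 12 for the September pair, 0 and 16 for coenosarc replicate 1 with the budding tip, and 4 and 2 for the budding tip with the mature polyp.

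Larger clusters that express these genes were argued against as the whole source: with fixed cluster profiles, cluster shares predicted a median of 0.209 of the log2 difference (95% bootstrap interval 0.146 to 0.253), and for 0 of 35 genes 0.8 or more. The prediction uses a single pooled profile per cluster, so a different mix of cells inside a cluster cannot be told from different expression. Depth was argued against, since 28 genes were called with every library thinned to the smallest total. The polyp grouping was picked because its 36 calls were the most of the 10 ways to set 2 libraries against 3, so that the next, 14 for the September pair, is no test of chance. Expression within clusters that differs in formed polyps is a candidate explanation; with 1 library per polyp stage, a difference between colonies stays open and was not tested.

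Genes with adjacent ID numbers often led the same cluster. Among 2797 genes seen in at least 25% of the cells of some cluster, 489 pairs had adjacent IDs, and both members of 123 pairs led the same cluster, at a level at least 4-fold above the other clusters' cells, against a median of 16 and a highest of 32 in 1000 shuffles of the ID order, which argues against chance placement. Cluster 20 held 48 of these pairs, cluster 13 held 13, cluster 22 held 9 and cluster 24 held 8. Reads of 1 gene split between identical copies were argued against as a general source, since the ratio of the pair members differed between libraries with a median chi-square per degree of freedom of 32.7, and 0 of 123 pairs were at 1.5 or below. If IDs follow position along the genome, which the files do not state, neighbouring genes may share a cell population, as tandem copies would; this was not tested.

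Gfa229200 and Gfa271980, chosen after their values were seen, were nearly missing in the budding tip (22 UMIs of Gfa229200) and mature polyp (14 UMIs) and present in both coenosarc libraries and the early polyp. Gfa229200 had 74.98, 83.9, 0.641, 55.9 and 0.833 CPM in the order coenosarc replicate 1, coenosarc replicate 2, budding tip, early polyp and mature polyp.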
